A study of Mus musculus with 6 samples.

How the data were processed

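RNA was sequenced from 6 murine pancreatic ductal adenocarcinoma cell lines named KPC142, KPC180, KPC469, KPC490, KPC630 and KPC850, with 1 library per line. Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit. The submitters' processing notes name Trimmomatic 0.36, STAR 2.7.10b, RSEM 1.3.3 and the genome build GRCm39. The deposited table holds the authors' expected counts, the estimates RSEM gives when reads that fit several transcripts are shared among them, for 56953 Ensembl genes. Between 5.28% and 5.66% of the table's cells in a library had a value, as deposited, with any fractional part (no tolerance), and these expected counts were rounded to whole numbers before use. How reads were shared between near-identical genes was examined only for genes nearly silent in 1 line.

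The study concerns how strongly CD8+ T cells enter tumours of these lines, but the labels give no infiltration class for any line. All 6 lines were therefore left without a group, and each is described by its own value or by the range and median over the lines. No comparison between groups was made. The edgeR quasi-likelihood test was not used, because without groups there is no contrast to test. The labels name no batch. Intervals given for ratios between libraries are exact conditional binomial 95% intervals and cover counting error only.

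Library totals ran from 16471558 to 18701274 counts. On these totals 1 count was worth 0.0535 to 0.0607 CPM, the unit of counts scaled to a common library total. The CPM values of genes use totals adjusted by the TMM factors given below, so they differ slightly from this. Where a gene had 0 counts in a line, its ratio was given as a bound against a floor of 3 counts in that library, which is 0.160 to 0.182 CPM. No pair of libraries was near-identical: the chi-square statistic per degree of freedom over genes ran from 82.1 to 172.9.

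Normalization used edgeR 4.0.16 in R 4.3.3, with TMM factors (0.986 to 1.01) and log2 CPM with a prior count of 2. The filter filterByExpr, at its defaults and with no design, kept 11531 genes. Without groups this filter asks for about 10 counts in every line and so removes genes that are silent in 1 line, Pcdh7 among them. Counts of genes are therefore also given for the 10234 genes with at least 10 CPM in at least 1 line, a setting fixed together with the filter. The genes named for each line were taken from all genes at that level. For the alternatives that change the filter, the TMM factors of the main filter were retained, a detail settled after the data had been seen.

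Gene symbols came from the GENCODE vM21 names, which matched 52029 of the 56953 identifiers. That annotation is built on GRCm38 rather than GRCm39, so it was used for names, chromosome membership and the order of genes, and no coordinate is given from it.

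Before the data were examined, 35 gene lists were fixed: 22 lists with a score, 4 panels and 9 lists of markers of other cell types. All listed symbols were found. A list's score in a line is the mean over its kept members of log2 CPM centred on each gene's mean over the 6 lines. The spread of a score over the lines and the mean pairwise correlation of its members were each placed among 10000 random lists matched on mean expression in 20 bins. These percentiles describe the libraries and are not p-values. The 95th percentile used to count lists and the size of 0.2 used to count chromosome medians were settled after the data had been seen.

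Named genes followed a rule fixed with the lists. It takes 10 genes of interest and the sex-chromosome genes, for each line the 3 genes with the largest gap above the next line and the 2 with the largest gap below it, and up to 4 kept members of each list with the largest range. Outside this rule, Epcam, Pcdh18, Fat1, Ptges, Kdr, Pax6, Cspg4, Ddx3x, Eif2s3x, Kdm5c, Kdm6a, Cdkn2b, Igf2bp3, Peg3 and the genes discussed with the silent genes were chosen after their values were seen. So were Cldn3, Ehf, Twist2 and Tnc. Some genes that the rule takes are not reported here.

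Correlations over the 6 lines are given as Pearson r and Spearman rho with two-sided exact permutation p-values over all 720 pairings, counting pairings with an absolute correlation as large. The smallest such p is 0.00139. Benjamini-Hochberg adjustment was made over 22 lists for Pcdh7 and over 12 pairs of lists. The number of genes following Pcdh7 was set against all 720 orders of its values in a one-sided exact test. Genes nearly silent in 1 line were examined for overlapping genes and for transcripts with at least 90% identity over at least 200 bases. The nearest gene with a median of at least 5 CPM on each side was also examined, and the lower one was used. Sets of genes matched on GC content, transcript length and expression were drawn 1000 times. Chromosome medians have bootstrap 95% intervals from 1000 draws of genes.

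The calculations were tested on simulated data. For line-specific genes, libraries were drawn from the real gene means and library sizes, with the same small scatter for every gene. Only well-expressed genes were changed, and no other gene was made to differ between lines. The simulated scores and lists were independent draws from normal distributions, without the shared variation of genes in real lines. Of 200 genes changed 6-fold in 1 line among 11531 genes, 182 were recovered as line-specific at 4-fold, all 200 of those changed 12-fold, and 3 of those changed 3-fold, with 0 wrong calls. Because no other gene was made to differ, the 0 wrong calls do not measure false calls among the real lines. For unrelated scores, 5.02% of 20000 simulated correlations had p under 0.05, against a nominal 4.86%. The first 2000 of these draws alone gave 6.05%, and the larger number was drawn after that value was seen. Of 200 simulated lists over 11531 genes, all 200 with a planted shift passed the 95th percentile, as did 12 without one.

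Alternatives were DESeq2 1.42.0 size factors, library totals alone, a prior count of 0.5, other filters, other list scores, rank correlation, other thresholds and each line left out in turn. Another definition of the two-sided p was added after the data had been seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps.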

Results

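Polyadenylated RNA of 6 murine pancreatic ductal adenocarcinoma (PDAC) cell lines was sequenced, with 1 library and no replicate per line. The lines carry the prefix KPC, the usual name of mouse PDAC models. Library totals were 16471558 counts in KPC142, 16715216 in KPC180, 18481045 in KPC469, 17206224 in KPC490, 18701274 in KPC630 and 17102700 in KPC850. The study asked which genes mark lines that induce low infiltration of CD8+ T cells and singled out PCDH7. The labels do not say which line induces which degree of infiltration, so the 6 lines are described side by side and no group is compared with another. Values of genes are in CPM, and list scores and chromosome medians are in log2 units. Intervals for ratios cover counting error only, and those for chromosome medians come from a bootstrap over genes.

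Pcdh7 (ENSMUSG00000029108), a protocadherin of the cell surface, differed widely between the lines. It reached 131.5 CPM in KPC850, 108.6 in KPC180 and 47.6 in KPC490, against 4.31 in KPC142, 3.78 in KPC630 and 0.109 in KPC469 (2 counts), with a median of 26.0 CPM. The ratio of the highest to the lowest line was 1207, with a counting interval of 333.7 to 9971. Of 5 kept genes among the related cadherins, 3 had a range of 4-fold or more. Celsr1 ran from 3.03 CPM in KPC180 to 139.8 in KPC142, and Fat2 from 0.708 in KPC469 to 18.9 in KPC180. Pcdh18 reached 54.7 CPM in KPC469 and 4.63 CPM or less elsewhere. Pcdh1 and Fat1 stayed within 2.05-fold and 1.66-fold over the 6 lines.

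**Figure D1:**
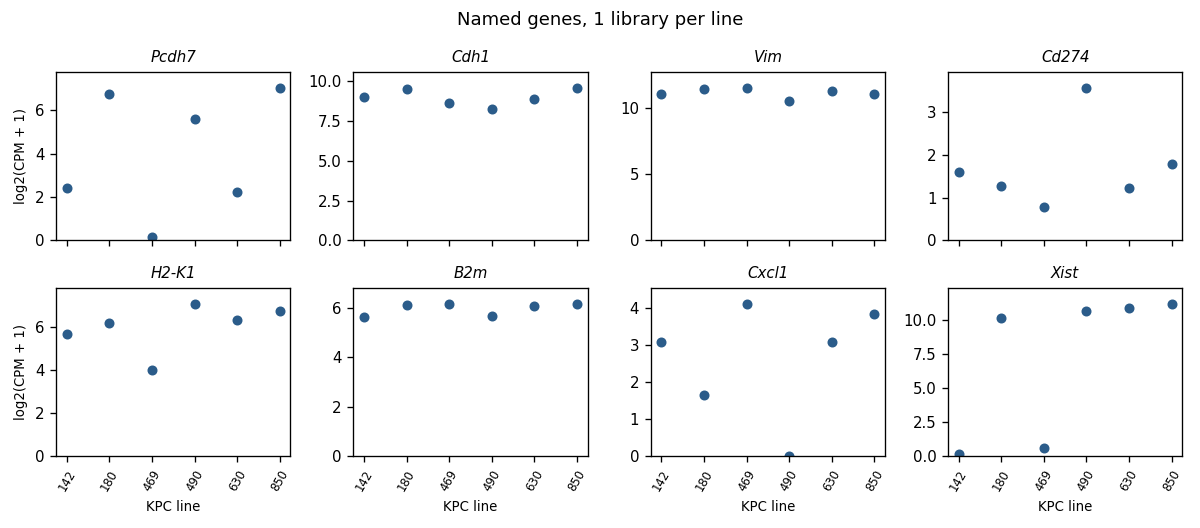
Expression of 8 named genes in the 6 KPC lines, as log2(CPM + 1) on the y axis, with 1 point per library and the line on the x axis. Pcdh7 runs from 0.109 CPM in KPC469 to 131.5 in KPC850, while B2m stays within 1.45-fold.

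Genes of the PDAC driver panel were expressed in every line. The tumour suppressor gene Trp53 lay between 143.5 CPM in KPC142 and 259.6 in KPC630, and Cdkn2a was lowest in KPC142 and reached 534.9 in KPC469, with a median of 288.8. Of the 15 genes in the driver panel, 1 had a range of 4-fold or more: Rnf43, an antagonist of Wnt signalling, with 1.58 CPM in KPC469 and 19.7 in KPC490.

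Over all 11531 kept genes, 1518 (13.2%) differed at least 4-fold between the highest and the lowest line, and the median range was 0.95 log2 units. Among the 10234 genes with at least 10 CPM in a line, 1577 (15.4%) did, and with every gene of at least 1 count kept the count was 5065. KPC469 stood farthest from the others, with a mean Spearman correlation of 0.918 to the other libraries. KPC490 and KPC630 were the closest pair at 0.961, and KPC469 and KPC850 the most distant at 0.908. The first principal component, 31.8% of the variance of the 1000 most variable genes, set KPC469 apart, the second (24.7%) KPC142 and the third KPC180.

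Each line had genes of its own. At 4-fold from the next line, 48 kept genes were higher in a single line, 25 of them in KPC469, and 79 were lower in a single line, 31 of them in KPC469 and 22 in KPC142. These counts depend on the filter, which removes genes silent in a line: among genes with at least 10 CPM in a line there were 161 higher and 102 lower, of which KPC469 had 78 and 36. KPC469 alone expressed Mgp, an inhibitor of calcification (29.8 CPM, 0 counts in the other 5 lines), and it had 40.3 CPM of the interferon-induced Ifitm1 and 87.1 of the potassium channel gene Kcnj2. It had 1.74 CPM of Wfdc2 against 348.8 to 598.4 in the others.

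KPC142 was the line with Y-linked transcripts, Eif2s3y at 11.6 CPM and Ddx3y at 10.3 CPM with 0 counts elsewhere, and it also had the cadherin gene Cdh16 (67.6 CPM, against 2.21 in the next line). It had 2 counts of Suclg2, a subunit of succinyl-CoA ligase, against 90.3 to 269.4 CPM elsewhere, and 0 counts of Zfp704. KPC180 expressed the incretin receptor gene Glp1r (57.1 CPM, 0.116 or less elsewhere), the procollagen peptidase gene Adamts2 (41.2 CPM) and the endocytic receptor gene Lrp2 (120.3 CPM). It had 0 counts of Amdhd2 and 1 count of Nexmif. KPC490 had 24.9 CPM of Ly6k with 0 counts elsewhere, 28.3 of Nepn and 17.7 of Efr3b. It had the least Col6a1, a collagen chain, at 4.12 CPM against 45.3 to 77.4, and the least Mal (9.87 CPM). KPC630 had 21.6 CPM of the smooth muscle actin gene Acta2, 17.0 of Hpgd, which degrades prostaglandins, and 14.3 of the chemokine gene Cxcl12. It had the least Ptprn (9.05 CPM) and Impact (11.5 CPM). KPC850 had 26.6 CPM of the basement membrane gene Nid2, 45.1 of Sult1c2 and 22.1 of Lbp, with 0 counts of Pttg1 (securin) and 3 counts of Repin1.

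The sex-chromosome panel split the lines further. Xist, the RNA that coats the inactive X, stood at 1124 to 2329 CPM in KPC180, KPC490, KPC630 and KPC850, at 0.120 CPM (2 counts) in KPC142 and at 0.545 CPM (10 counts) in KPC469. Kdm5d and Uty had 123 and 96 counts in KPC142 and 0 in the other 5 lines, KPC469 included.

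Epithelial and mesenchymal genes varied strongly. The epithelial score ran from -0.82 in KPC469 to 0.69 in KPC850, and the mesenchymal score from -0.77 in KPC490 to 0.94 in KPC469. Of 17 kept epithelial genes 10 had a range of 4-fold or more, among them the tight junction gene Tjp3 (1.34 CPM in KPC180, 67.0 in KPC850) and the keratin Krt7 (140.5 in KPC469, 2572 in KPC630). Of 14 kept mesenchymal genes 10 did, among them Cdh2 (N-cadherin), at 0.599 CPM in KPC142 against 62.8 to 156.9 elsewhere, and S100a4 (33.3 in KPC630, 1222 in KPC469). Cdh1 (E-cadherin) and Vim (vimentin) varied by 2.57-fold and 1.98-fold only. Below the filter, Epcam was low but varied widely, from 0.243 CPM in KPC180 to 10.5 in KPC630, a ratio of 43.2 (16.6 to 160.1). The filter left 3 epithelial genes, Epcam among them, and 6 mesenchymal genes with at least 10 CPM in a line out of the scores. All of these had a range of 4-fold or more. The 3 epithelial genes, Epcam, Cldn3 and Ehf, were lowest in KPC180 (0.243, 0 and 0.425 CPM) and higher in KPC469 (4.58, 0.599 and 33.2 CPM). Of the 6 mesenchymal genes, Twist2 and Tnc were highest in KPC490 (11.7 and 13.5 CPM), and none was lowest there. The lowest line of each score may thus depend on the filter. Over the 6 lines the 2 scores had r = -0.628 (exact permutation p = 0.178, adjusted 0.356) and rho = -0.543 (p = 0.297, adjusted 0.446). Without the 2 lines farthest from the epithelial median r was -0.257. Such values, here and below, leave out 2 lines, rest on the other 4 only and have no p-value.

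The classical PDAC programme was lowest in KPC142 (-0.98) and highest in KPC180 (0.45), and 13 of its 18 kept genes had a range of 4-fold or more. Cldn18, a claudin of gastric-type epithelium, stood at 1.32 CPM in KPC142 and 1.75 in KPC850 against 360.6 to 504.1 in the other 4 lines. Foxa1 ran from 3.06 in KPC142 to 69.6 in KPC490, and Tff1 from 17.5 in KPC490 to 440.3 in KPC850. The basal-like score ran from -0.43 in KPC180 to 0.46 in KPC850, with Krt14 at 0.728 and 37.3 CPM in the same lines. Its members did not vary together beyond random lists (percentile 88.9).

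Cholesterol synthesis was the list whose members varied most closely together, with a mean pairwise correlation of 0.864. All 20 members were lowest in KPC469, whose score was -1.31, and the score was -0.46 in KPC630 and 0.24 to 0.63 in the other 4 lines. Of the 20 genes, 13 had a range of 4-fold or more. Sqle, which makes squalene epoxide, ran from 71.9 CPM in KPC469 to 519.4 in KPC490, a ratio of 7.22 (6.82 to 7.66). Lss, the lanosterol synthase gene, ran from 33.5 to 226.4 in the same lines.

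Glycolysis and hypoxia scores were highest in KPC490 (scores 0.44 and 0.60) and low in KPC469 (-0.50 and -0.33) and KPC180 (-0.32 and -0.39). Of 18 kept glycolysis genes 3, and of 19 hypoxia genes 7, had a range of 4-fold or more. The lactate exporter gene Slc16a3 ran from 4.52 CPM in KPC469 to 228.8 in KPC850, and Egln3, a prolyl hydroxylase, from 0.607 in KPC180 to 65.5 in KPC850. With shared genes left out, the 2 scores had r = 0.923 (exact permutation p = 0.00833, adjusted 0.05) and rho = 0.943 (p = 0.0167, adjusted 0.2). Without the 2 lines farthest from the hypoxia median r was 0.972. An adjusted p of 0.05 is not under the threshold of 0.05. Keeping every gene with at least 1 count, the adjusted exact p was 0.0167, the lowest over the alternatives, which reached 0.2.

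H2-K1 and H2-T23, heavy-chain genes of MHC class I, were lowest in KPC469. H2-K1 stood at 14.9 CPM there against 49.97 to 134.9 in the other lines (ratio of highest to lowest 9.03, 7.97 to 10.3), and H2-T23 at 6.92 against 18.9 to 45.7. B2m, the class I light chain, varied by 1.45-fold and was highest in KPC469 (70.9 CPM). Of 13 kept members 2 had a range of 4-fold or more, and the score ran from -0.31 in KPC469 to 0.29 in KPC630, a spread at percentile 94.5 of random lists. The epithelial and class I scores had r = 0.942 (exact permutation p = 0.00694, adjusted 0.05) and rho = 0.886 (p = 0.0333, adjusted 0.2). Without the 2 lines farthest from the epithelial median r was 0.905. With the median over members in place of the mean r was 0.445, and with the mean of z-scores 0.573.

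The type I interferon score was lowest in KPC469 (-0.80) and highest in KPC850 (0.50). Oasl1 ran from 5.72 to 64.6 CPM in these lines, 3 of 11 kept genes had a range of 4-fold or more, and 14 of the 30 listed genes stayed under 1 CPM in every line. The interferon and nucleic acid sensing scores had r = 0.835 (exact permutation p = 0.0389, adjusted 0.129) and rho = 0.829 (p = 0.0583, adjusted 0.233). Without the lines farthest from the interferon median r was 0.631. The sensing score ran from -0.19 in KPC469 to 0.25 in KPC850, a spread at percentile 36.9. Its members did not vary together, with a mean pairwise correlation of -0.11 (percentile 0.77 of random lists). Of its genes, the kinase gene Ikbke ran from 2.83 CPM to 69.1 in the same lines.

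T-cell-attracting chemokines were mostly silent: 10 of 13 stayed under 1 CPM in every line. Cxcl16 ran from 6.19 CPM in KPC180 to 36.3 in KPC630, and Cx3cl1 from 28.0 in KPC630 to 80.7 in KPC180. The score of the 2 kept genes ran from -0.53 in KPC180 to 0.53 in KPC850 (percentile 78.9). Among ligands and enzymes that inhibit T cells, 5 of 12 kept genes had a range of 4-fold or more, with a score from -0.35 in KPC142 to 0.20 in KPC490 (percentile 87.7). Cd274 (PD-L1) was at 10.8 CPM in KPC490 and at 0.708 to 2.45 in the other lines. Nt5e (CD73), which makes adenosine, ran from 5.83 in KPC469 to 106.0 in KPC850. Ptgs2 (COX-2) was lowest in KPC630 at 18.4 and highest in KPC469 at 259.2, while Ptges, the prostaglandin E synthase gene, had 0.545 CPM in KPC469 against 65.7 to 125.4 elsewhere (chosen after its values were seen).

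Myeloid-attracting cytokines and NF-kB targets were lowest in KPC180 (scores -0.79 and -0.46) and highest in KPC630 (0.43 and 0.30). Of 9 kept cytokine genes 5, and of 14 NF-kB targets 3, had a range of 4-fold or more. Cxcl5 ran from 2.25 CPM in KPC180 to 194.6 in KPC850, and Csf1 from 7.84 in KPC490 to 103.7 in KPC469. Cxcl1, a neutrophil chemoattractant, had 0 counts in KPC490 and 2.12 to 16.4 CPM elsewhere, at least 94.1-fold between KPC469 and KPC490. It is not part of either score. The filter left out 3 cytokine genes with at least 10 CPM in a line, Cxcl1 among them, and 1 such NF-kB target, also Cxcl1. The 2 scores had r = 0.843 (exact permutation p = 0.0431, adjusted 0.129) and rho = 0.714 (p = 0.136, adjusted 0.327). Without the 2 lines farthest from the NF-kB median r was 0.887. Leaving out KPC180 gave r = 0.423.

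Of the 22 lists, 16 spread over the lines more than 95% of random lists did, and 13 had members that varied together more than in 95% of them. TGF-beta and YAP/TAZ scores were highest in KPC180 (0.44 and 0.50) and lowest in KPC142, with the YAP/TAZ target Ankrd1 from 43.1 CPM in KPC490 to 377.9 in KPC180. Of these lists 4 of 16 and 8 of 22 kept genes had a range of 4-fold or more. RAS/MAPK output, with 5 of 21 such genes, was lowest in KPC142 (-0.49), where Epha4 had 8.15 CPM against 20.3 to 137.7. The proliferation score was highest in KPC630 (0.37), the highest line for 24 of 31 members. The ribonucleotide reductase gene Rrm2, at 701.5 CPM there and 165.9 in KPC469, was the 1 member with a range of 4-fold or more. The unfolded protein response score was highest in KPC142 (0.43), where 11 of 20 members were highest, with Trib3 at 74.1 CPM and 8.79 in KPC630. NRF2 scores ran from -0.24 in KPC490 to 0.33 in KPC850, with 4 of 17 genes at 4-fold or more, and Nqo1 ran from 5.40 in KPC490 to 48.3 in KPC142. The p53 targets did not stand apart from random lists (percentile 69.0), with 4 of 21 genes at 4-fold or more and Gdf15 from 1.52 to 8.48 CPM. Of 12 Wnt targets 3 were kept, with a score from -0.68 in KPC469 to 0.52 in KPC490 (percentile 73.2). Over the 12 pairs of scores examined, 0 passed an adjusted p of 0.05, and those not given above had adjusted permutation p-values of 0.133 to 0.903 for Pearson r and 0.308 to 1 for Spearman rho.

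**Figure D2:**
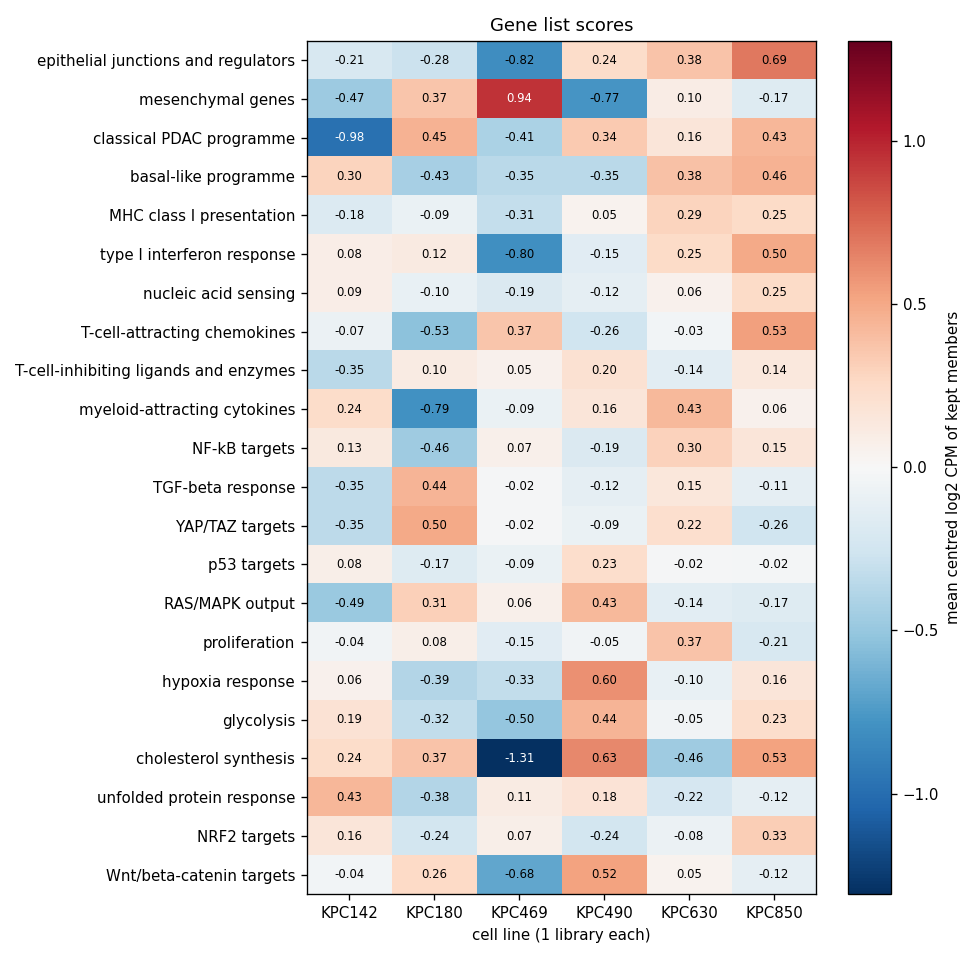
Scores of the 22 gene lists (rows) in the 6 lines (columns), as the mean centred log2 CPM of the kept members, in colour and in numbers. KPC469 has the lowest cholesterol synthesis score (-1.31) and the highest mesenchymal score (0.94).

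None of the 22 list scores followed Pcdh7 after adjustment. A single list could pass only at the smallest exact permutation p, 0.00139 (adjusted 0.0306), so a relation is not excluded. The strongest relation was with cholesterol synthesis: r = 0.912 (exact permutation p = 0.0111, adjusted 0.244 over 22 lists) and rho = 0.829 (p = 0.0583, adjusted 0.981). Without the lines farthest from the Pcdh7 median r was 0.713, and without KPC469 alone it was 0.751. Wnt targets had r = 0.740 (exact permutation p = 0.0917, adjusted 0.642) and rho = 0.314 (p = 0.564, adjusted 0.981), with r = 0.787 without those lines. Interferon genes had r = 0.736 (exact permutation p = 0.0833, adjusted 0.642) and rho = 0.6 (p = 0.242, adjusted 0.981), and r was -0.499 without those lines, so the relation rests on them. For the basal-like list the lines fell into separate clusters, so no pooled value is given. Across the transcriptome, 54 of 11531 genes had an absolute r of at least 0.95 with Pcdh7, 26 rising and 28 falling with it. As many genes were found under 195 of the 720 orders of its values (one-sided exact p = 0.271), with a median of 38. With each line left out in turn the number was 144 to 230, as a high r is easier to reach over 5 lines.

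Median expression by chromosome also differed between the lines. Of 120 medians for a chromosome in a line, 23 were 0.2 or more log2 units from the median of the lines, 9 above and 14 below. Genes of chromosome 4 lay 0.50 above in KPC142 (0.46 to 0.54, 686 genes) and at -0.25 in KPC469. Genes of chromosome X lay at -0.46 in KPC850 (-0.49 to -0.41, 330 genes). Chromosome 8 was at 0.34 in KPC180, 0.23 in KPC142 and 0.19 in KPC469, against -0.21 to -0.25 in the other 3 lines. Chromosome 10 was at 0.33 in KPC490 and chromosome 18 at 0.32 in KPC180.

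**Figure D3:**
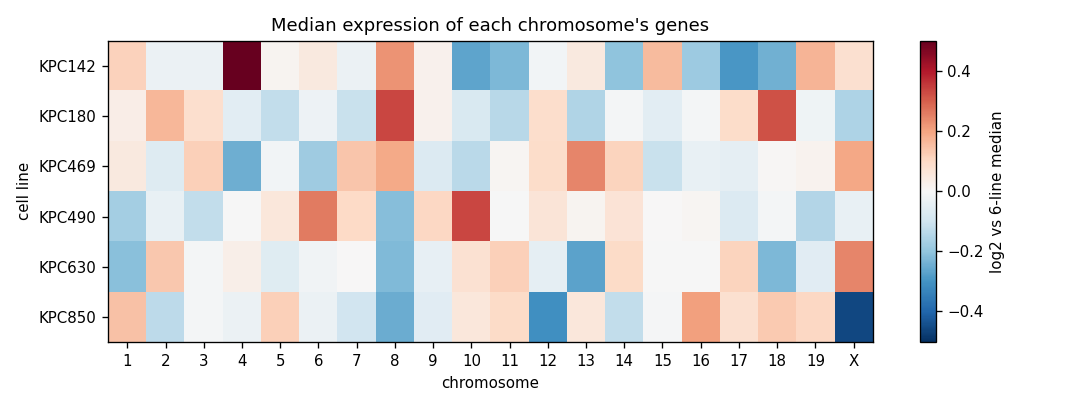
Median log2 CPM of each chromosome's kept genes relative to the median of the 6 lines (colour), with chromosomes on the x axis and lines on the y axis. Chromosome 4 in KPC142 (0.50) and X in KPC850 (-0.46) are the extremes.

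Most markers of other cell types stayed under 1 CPM in every line. T and NK cell genes reached 0.755 CPM at most, B cell genes 0.0607, erythroid genes 0.160, endothelial genes 2.502 (Kdr), endocrine genes 7.10 (Pax6 in KPC180) and fibroblast genes 9.09 (Cspg4 in KPC850). Of the acinar genes Cela1 reached 20.6 CPM in KPC180 and the other 13 stayed under 1 CPM. Of the macrophage list, Mrc1 (15.3 to 159.9 CPM) and Cd14 (25.2 to 138.9) were expressed in every line, and 11 of the 14 genes stayed under 1 CPM. Of the glial list Mbp was at 25.1 to 73.4 CPM, and 5 of 7 genes stayed under 1 CPM. All 4 kept oncofetal genes had a range of 4-fold or more: Igf2bp1 ran from 1.53 in KPC469 to 144.0 in KPC180, and Hmga2 from 88.6 in KPC142 to 519.0 in KPC180.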

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

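The gap test was planned, and no test in this part was chosen only after its result was seen.

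The share of mitochondrial counts in KPC142, 1.61%, lay apart from the 2.07% to 2.23% of the other lines, by a gap of 0.744 of the whole range, above the 95% critical value for 6 samples. It was 1 of 26 measures examined this way, and chance alone gives about 1 in 20, or 1.3 of 26.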

How the results depend on the processing

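The test with a two-sided p taken from the smaller tail was chosen only after the results were seen, as was the choice of which single correlations and score to follow. The other alternatives were planned. Of 152 values computed under the alternatives, 133 kept their side of the threshold or stayed within the spread allowed (1.5 times for counts), 19 did not, and 0 reversed. Of these 133, 40 correlation results say nothing about stability, because a single relation was unable to pass there. The correlations did not pass in the main setting, so the rest kept their side by not passing, however far r fell. The epithelial and class I relation counted as kept with r = 0.942 in the main setting and 0.445 with the median over members. The count of 1518 genes with a 4-fold range was 5065 with every gene of at least 1 count kept and 613 at 8-fold, and 1108 to 1387 with a line left out. The count of 127 line-specific genes was 263 both with every such gene kept and with at least 10 CPM in a line, 31 at 8-fold, and 117 to 165 with a line left out. These moves follow from which genes are tested and from the threshold. The number of pairs of lists under an adjusted p of 0.05 was 0, and 1 with every gene kept, namely hypoxia with glycolysis; the cause was not tested. Under the other two-sided p the smallest adjusted p over pairs was 0.0667. The 54 genes following Pcdh7 became 104 with every gene kept, 225 at an absolute r of 0.9 and 223 at a rank correlation of 0.9. With a line left out they numbered 144 (without KPC850) to 230 (without KPC630), since a high r is easier to reach over 5 lines, and the exact p ran from 0.0583 to 0.567. The counts of lists with a wide spread (16) and of chromosome medians (23) stayed within 13 to 17 and 22 to 23. The number of lists following Pcdh7 was 0 under the other scalings, filters and list scores. There a single list could pass only at the smallest exact permutation p, 0.00139 (adjusted 0.0306), so this 0 does not exclude a relation. With a line left out the smallest adjusted p for a single list is 0.183, and by rank correlation or the other two-sided p it is 0.0611, so these settings were unable to call a single list. For a single pair it is 0.1 with a line left out. The cholesterol synthesis score of KPC469 ranged from -1.18 to -1.40 with another line left out, since scores are centred on the lines used. With 1 library per line, no alternative measures how far a line's values would vary between cultures.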

Other observations

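The tests of neighbouring genes were chosen only after their results were seen, and the 3 patterns and the definition of silent genes were also chosen from the data. The labels put no line in a group, so no biological explanation by group was tested, and changes of the genome were examined through expression alone.

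Basal-like scores fell into separate clusters: 0.30 in KPC142, 0.38 in KPC630 and 0.46 in KPC850, against -0.43 in KPC180, -0.35 in KPC469 and -0.35 in KPC490. Of X-linked genes known to escape inactivation, Ddx3x lay between 807.2 and 1108 CPM, Eif2s3x between 194.7 and 399.6, Kdm5c between 155.7 and 265.0 and Kdm6a between 46.3 and 83.9. Peg3, an imprinted gene, stood at 12.3 CPM in KPC490 and 15.2 in KPC630 and at 0.180 or less in the other 4 lines, and Igf2bp3 ran from 0.300 in KPC142 to 59.9 in KPC490. Peg3 and Igf2bp3 were chosen after their values were seen, as were these X-linked genes.

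In all, 11 protein-coding genes had 0 to 3 counts in 1 line and at least 10 CPM in each of the other 5 lines: 4 in KPC142 (Suclg2, Zfp704, Cpne8, Fermt2), 3 in KPC469 (Rangrf and Slc25a13 among them), 2 in KPC180 (Amdhd2, Nexmif) and 2 in KPC850 (Pttg1, Repin1). Reads counted on an overlapping gene or a near-identical copy instead would raise that partner. Of the 8 genes with a partner, 0 had one that gained 50% of the missing level, which argues against this for the partners found. Partners were searched only in the GENCODE vM21 annotation, so any partner absent from it would be missed. Loss of a segment that holds several neighbouring genes would lower the neighbours. The lower of the nearest expressed genes on each side was under 25% of its usual level for 2 of the 11 genes. The share of all expressed genes with such a neighbour in the same lines would give 0.422. For the other 9 genes no such neighbour was this low, which argues against loss of a segment that reaches these neighbours. The 2 genes with a low neighbour, both in KPC142, were Zfp704 with Zbtb10 (0.0599 CPM against 14.4) and Cpne8 with Kif21a (0 CPM against 12.3). They lay in runs of 3 and 2 consecutive low genes, counting only genes with a median of at least 5 CPM. Pag1, near Zfp704, had a median of 1.32 CPM and was not counted. It had 1 count in KPC142 and 20 to 873 counts in the other lines. Mrps28 and Tpd52, also near Zfp704, were not low in KPC142 (27.3 and 205.6 CPM, against medians of 22.8 and 181.1). For Zfp704 and Cpne8 alone, loss of a segment that holds several neighbouring genes may be the cause. It cannot be told apart from silencing, because the runs are short and DNA was not analysed here.

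Chromosome 4 in KPC142 and chromosome X in KPC850 had the largest shifts among the 120 medians, 0.50 and -0.46 log2 units. Genes of other chromosomes matched on GC content, transcript length and expression had medians of -0.0127 in KPC142 and -0.0075 in KPC850, which argues against such a bias. Along the chromosome, 9 of 10 blocks of genes on chromosome 4 and 10 of 10 on X carried at least 50% of the shift, the exception being block 4 of chromosome 4 (median -0.14), which holds Cdkn2a (-0.53), Mtap (-1.09) and Cdkn2b (0.055). Not every X-linked gene was low in KPC850, where Xist was higher than in the other lines (2329 CPM) and Eif2s3x (282.3 CPM) and Kdm5c (220.9 CPM) lay above their medians of 258.1 and 209.6, while Ddx3x (807.2 CPM) and Kdm6a (62.95 CPM) lay below theirs of 845.5 and 64.48. A candidate explanation, as a hypothesis, is a change that covers most or all of the chromosome, in copy number or in regulation, and DNA, which would tell these apart, was not analysed here.

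The cholesterol synthesis score of KPC469 was -1.31. Genes matched on GC content, transcript length and expression had a score of -0.0327 there (95% range -0.27 to 0.15), which argues against such a bias. Differences in culture were not examined and stay open.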
